A study of Mus musculus with 32 samples.

How the data were processed

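The values used here are the deposited FPKM tables (mapped fragments scaled to transcript length and library size), 1 for embryonic stem cells and 1 for embryos, computed by the authors with TopHat2 2.0.10, Bowtie2 2.1.0 and Cufflinks 2.1.1 on mouse build mm9 per the submitters' processing notes. The unit is not written in the table headers; it was taken from the named tool and from the values, which are not whole numbers and do not sum to a fixed total. Sequencing depth is unknown, because a table of FPKM carries no read counts. Each table listed 23174 loci, and 250 of them carried a symbol that occurred more than once. For a repeated symbol the locus with the highest mean FPKM was kept, which left 22924 genes. All 32 columns were used.

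The stem-cell table held 18 libraries in 9 groups of 2, and the embryo table held 14 libraries in 8 groups. Replicates are libraries with the same label. The labels do not say whether replicates came from separate cultures or injections, so the p-values measure the spread between libraries, which may be technical only. The 2 libraries labelled DR++ EV differed by an SD of 0.117 in log2 ratio for genes between 10 and 30 FPKM and the DR++ MERVL pair by 0.0937, while the other stem-cell pairs ranged from 0.312 to 1.25. The main stem-cell fit pooled the spread of each gene over all 9 groups, so these similar pairs lower it for every comparison. Only in fits on the compared groups can DR++ p-values rest on these pairs alone.

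Values were turned into log2(FPKM + 1). A gene was tested when it had at least 1 FPKM in at least 2 libraries of the fit. Linear models with moderated variances were fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison. A gene was called at an adjusted p under 0.05. The stem-cell fit used 18 libraries, 9 residual degrees of freedom and 12624 genes. The 8-cell embryo fit used 11 libraries, 6 residual degrees of freedom and 13298 genes, and it assumed that the lone control 8-cell library varied as much as the others. The stage comparison set 4 two-cell libraries against 5 normal-morphology 8-cell libraries, with 7 residual degrees of freedom and 13014 genes. Only the 8-cell embryos had been injected, and the two-cell libraries were submitted at another time, so stage, injection and batch are confounded there and in the two-cell-embryo and 8-cell lists. Blastocyst groups had 1 library each, so no p-values were computed for them. For those groups the median difference of a list was placed among 10000 random lists matched for expression, which is descriptive and has no replicate check. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

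There were 13 gene lists, written from general knowledge before the data were examined: two-cell-stage genes, pluripotency, trophectoderm, primitive endoderm, primed and germ-layer genes, the corepressor group around Zmym2 and Kdm1a, germline, imprinted, maternal-effect, compaction and epithelial, stress and p53, fibroblast markers, and cumulus-cell markers. Each list was tested with camera at a preset correlation of 0.01 and again with a correlation estimated from the residuals, and fry was run beside it. List p-values were adjusted over the lists of a comparison. Further lists were taken from the data. The Zmym2-higher and Zmym2-lower lists held up to 100 genes each, called in Gt/Gt against wild type. The two-cell-embryo and 8-cell lists held up to 200 genes each, called with an absolute log2 fold change of at least 2 between stages.

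Genes were named by a rule. Zmym2, Kdm1a and Dux were always looked up. In each comparison the 8 largest rises and the 8 largest falls were taken among called genes whose libraries did not overlap. Predicted-gene symbols, small-RNA loci and genes averaging under 1 FPKM in both groups were left out of those 16. For each list with at least 3 called members, or with an adjusted camera p under 0.05, up to 4 called members with the largest changes were added. In blastocysts the 4 list members with the largest absolute differences of at least 1 were taken. Genes listed at 0 in a whole group but abundant elsewhere (Eef1a1, Dppa3, Map1lc3b and Bc1) were left out of this rule, of the derived lists, and of list medians by library and in blastocysts. Genes outside the rule are marked in the text as chosen after their values were seen. Members of the Zscan4, Usp17l, Tdpoz, Rhox and Gm families share reads between near-identical copies, so values of single copies are uncertain.

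The alternatives were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, median-ratio size factors, fits on the compared groups only, no variance trend, a replicate block, a minimum absolute log2 fold change of 1, removal of each library in turn, an estimated correlation for camera, and shorter derived lists of 100 and 50 genes. Fits lacking the DR++ EV libraries, fits with DR++ UT as the control, a fit lacking two-cell embryos, and removal of genes listed at 0 across a group were chosen after the data had been seen.

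In a self-test of 5 comparisons, the code was run on values simulated from fitted group means and spread. Compared groups had 1 mean, with known fold changes added to 200 random genes. Spread was pooled over groups, unlike in real pairs, so real rates may differ. For Gt/Gt against wild type, over 12497 genes, 43.3% of the genes shifted by a log2 fold change of 1 were called, 91% at 2 and 100% at 3, and 17 of 173 calls were false. For CRISPRa MERVL against its control, over 12516 genes, the shares were 26.9%, 83.6% and 100%, with 3 of 143 calls false. For siZmym2 against control 8-cell embryos, over 12933 genes, the shares were 0%, 0% and 27.3%, with 0 of 18 calls false. For arrested against normal siZmym2 embryos, over 12865 genes, they were 0%, 34.3% and 84.8%, with 2 of 81 calls false. For two-cell against 8-cell embryos, over 9575 genes, they were 23.4%, 94% and 98.5%, with 8 of 151 calls false.

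Comparisons that use the same control share its noise. For these, overlaps of called genes were compared with the product of the group sizes over the number of genes and with 100 simulations in which only the shared control noise links the results. The simulations hold no changed genes and so gave a mean overlap of 0 by construction, and only their covariance is used for comparison. The test of Y loss replaced, after the values were seen, one that the observation itself would have met, and its bounds were set with the values known. They were then added to the test of an XX line, which had been met on the X median alone. With 2 control libraries the controls cannot be split between comparisons, so part of any excess may come from the shared controls. Repeat families such as MERVL are not in the gene tables and were not analysed here. Loci for miR-344 and miR-344-2 were listed at 0 in all libraries of these polyA-selected and full-length cDNA preparations, so mature microRNA levels were not measured. The DR++ and the unsorted CRISPRa libraries were submitted at different times, so that contrast is confounded with batch.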

Results

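The data are 32 mouse RNA-seq libraries of unknown depth, given as FPKM. The 18 stem-cell libraries form 9 groups of 2: Zmym2 wild-type and Zmym2 Gt/Gt gene-trap cells, CJ7 cells with CRISPR activation (CRISPRa) of an empty vector (EV), MERVL or miR-344-2, and a sorted population labelled DR++ that was untreated (UT) or carried EV, MERVL or miR-344-2. The 14 embryo libraries are 4 of two-cell embryos, 2 of 8-cell embryos with miR-344 mimic, 2 of normal siZmym2 8-cell embryos, 2 of arrested siZmym2 embryos, 1 control-injected (NC) 8-cell library, and 1 blastocyst library each for mimic, siZmym2 and NC. Values below are FPKM as mean ± SD with n = 2 libraries per group unless stated, and changes are log2 fold changes. Counts are of genes called by limma at the adjusted level given in the processing notes.

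Zmym2 (mm9 chromosome 14, start 57506631, end 57581416), which encodes an MYM-type zinc-finger protein found in LSD1-CoREST complexes, was read first in every sample. In replicates 1 and 2 it was listed at 17.4 and 33.5 FPKM in wild-type cells and at 3.29 and 8.32 in Gt/Gt cells. The CRISPRa pairs gave 14.8 and 41.5 (EV), 12.2 and 26.4 (MERVL), and 11.2 and 24 (miR-344-2). The DR++ pairs gave 20.6 and 24.3 (UT), 24.1 and 22.8 (EV), 19.4 and 19 (MERVL), and 21.6 and 30.8 (miR-344-2). In embryos Zmym2 was listed at 2.82 in the NC 8-cell library, 1.05 and 0.914 in siZmym2 8-cell, 0.973 and 1.07 in arrested, and 1.44 and 2.44 in mimic libraries. Blastocysts gave 1 (NC), 0.786 (siZmym2) and 1.35 (mimic), and two-cell embryos 7.85, 8.35, 7.86 and 10.2. Zmym2 was not called in Gt/Gt cells (log2 fold change −1.99, SE 0.534, adjusted p = 0.0706), although it was with a replicate block, nor in siZmym2 8-cell embryos (−0.947, adjusted p = 1). Kdm1a (chromosome 4, start 136106447, end 136158638), the LSD1 demethylase gene, was not called in any comparison before rescaling. It was at 107 ± 17.1 in Gt/Gt and 80.7 ± 23.7 in wild-type cells.

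**Figure D1:**
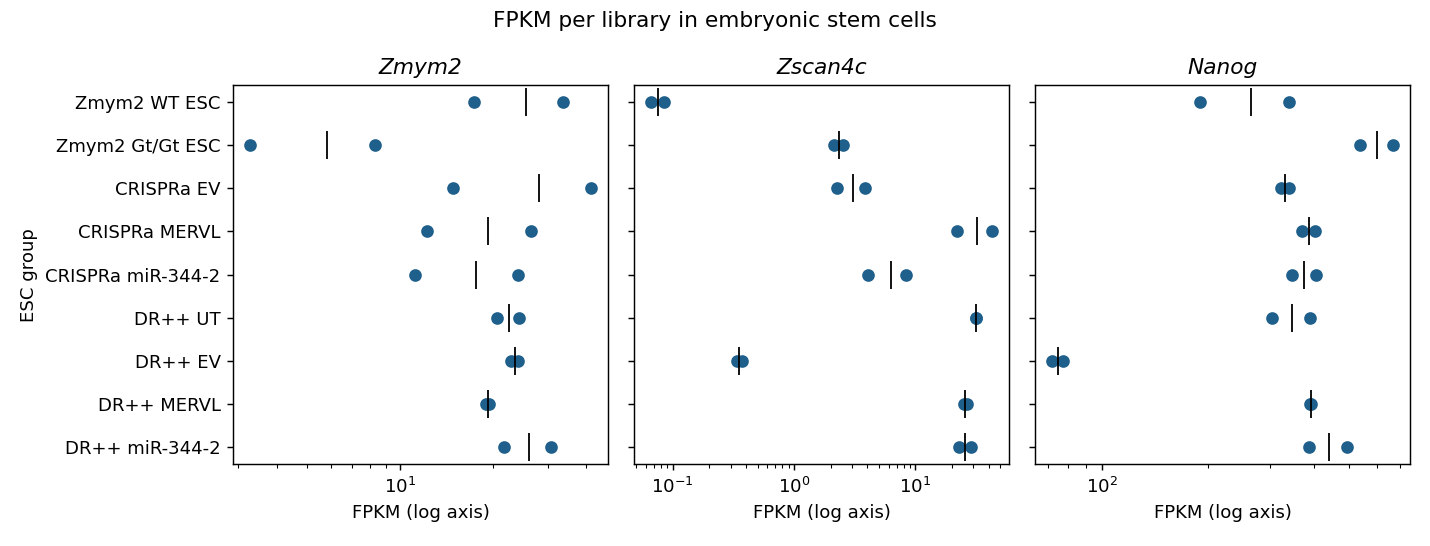
FPKM of Zmym2, Zscan4c and Nanog in each of 18 stem-cell libraries, by group, on a log axis; bars are means of n = 2. Zmym2 was at 3.29 and 8.32 in Gt/Gt cells, and Zscan4c at 0.354 ± 0.0243 in the libraries labelled DR++ EV.

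The first question was which genes differed in cells carrying the Zmym2 gene trap. Usp26 (chromosome X, start 49107135, end 49154410), a germ-cell deubiquitinase gene, rose from 0.504 ± 0.0968 to 31.3 ± 12.3 FPKM (log2 fold change 4.37, adjusted p = 5.02e-06). Arl14epl (chromosome 18, start 47081468, end 47093876), an oocyte and early-embryo transcript, rose from 3.64 ± 2.71 to 59.2 ± 6.64 (3.83). Sohlh2, a germ-cell transcription factor gene, rose from 4.64 ± 2.01 to 50.9 ± 0.615, and Tuba3a, a testis tubulin gene, from 6.74 ± 0.484 to 54.2 ± 14.3. Ube2l6, an ISG15-conjugating enzyme gene, rose from 1.84 ± 1.08 to 26.3 ± 2.15, Fam25c from 32.6 ± 10.5 to 284 ± 38.1, and Tex13 from 0.00953 ± 0.0135 to 5.57 ± 0.35. Among the largest falls were Ddx3y (chromosome Y, start 597157, end 623056; −4.24) and Eif2s3y (−4.05), both Y-linked, and Pnp2, a purine-salvage gene (36.8 ± 13.9 to 1.1 ± 0.0992). Tagln and Acta2, contractile genes, fell by 3.38 and 3.03, and Olig2 and Olig1, neural transcription factor genes, by 3.45 and 3.35.

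Of 33 tested two-cell-stage genes, 9 rose and 1 fell in Gt/Gt cells over all genes, and 18 rose and 1 fell adjusted over the list alone. Gm5662 (6.3 ± 2.22 against 0.326 ± 0.257), Gm2016 (1.91), Gm8994 (1.8) and Gm5039 (1.79) rose. Zscan4c (chromosome 7, start 11591093, end 11595896), chosen after its values were seen, rose from 0.0760 ± 0.0132 to 2.34 ± 0.265. The list median was 0.487 with 32 genes positive, and camera gave adjusted p = 7.88e-16, but adjusted p = 0.0894 with an estimated correlation. The germline list had 4 genes higher and 0 lower of 26, among them Sohlh2, Tuba3a, Tuba3b (1.02) and Fkbp6 (1.02). It had 8 higher and 0 lower adjusted over the list alone and a median of 0.41 (adjusted p = 6.29e-07, or adjusted p = 0.184 with an estimated correlation).

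Pluripotency genes moved in both directions in Gt/Gt cells, with 3 higher and 1 lower of 26 (6 and 2 adjusted over the list alone; list adjusted p = 0.0603). Nanog (chromosome 6, start 122657585, end 122663796), a core factor of naive pluripotency, rose from 264 ± 105 to 604 ± 94.5, Prdm14 from 4.91 ± 0.698 to 13.1 ± 0.951 and Tcl1 from 19.5 ± 4.36 to 52.7 ± 14.5, while Zfp42 fell from 440 ± 241 to 104 ± 6.53. Trophectoderm genes had 0 higher and 4 lower of 18 (1 and 7 adjusted over the list alone). The epithelial keratin genes Krt8 (51.9 ± 10.6 to 7.42 ± 2.92) and Krt18 (45.2 ± 1.65 to 7.01 ± 2.57) fell, as did Krt7 (−1.61) and Fgfr2 (−1.07), and the list gave adjusted p = 8.12e-05 (adjusted p = 0.339 with an estimated correlation). In primitive endoderm 1 gene rose and 4 fell of 16 (1 and 8 adjusted over the list alone), including Dab2 (3.77 ± 1.64 to 0.361 ± 0.0787), Lrp2 (−1.3) and Cubn (−0.964). The median was −0.912, or −1.75 in replicate 1 and −0.296 in replicate 2 (adjusted p = 1.26e-08, or adjusted p = 0.184 with an estimated correlation). Primed and germ-layer genes had 0 higher and 5 lower of 15, the same adjusted over the list alone. The methyltransferase genes Dnmt3b (68.3 ± 32.3 to 24.3 ± 1.85) and Dnmt3a (27.6 ± 6.76 to 11.4 ± 1.39), Lef1 (−1.69) and Pax6 (−1.61) fell (adjusted p = 7.16e-06, or adjusted p = 0.184 with an estimated correlation). Imprinted genes had 0 higher and 3 lower of 19 (2 and 8 adjusted over the list alone): Grb10 fell from 66.9 ± 25.7 to 8.78 ± 2.52, Cdkn1c from 24.3 ± 4.41 to 8.07 ± 3.56 and Sfmbt2 by 1.78 (adjusted p = 0.000411, or adjusted p = 0.0894 with an estimated correlation).

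Of 23 compaction genes, Amot alone fell (−0.748) in Gt/Gt cells, with a list median of −0.131 and adjusted p = 0.0325 (adjusted p = 0.456 with an estimated correlation), and the median was 0.0572 (adjusted p = 0.731) without wild-type replicate 1. None of 31 corepressor genes was called (median −0.14, adjusted p = 0.241). Fibroblast markers had 1 gene higher and 2 lower of 15, with medians of −1.9 in replicate 1 and −0.119 in replicate 2 (adjusted p = 7.19e-05, or adjusted p = 0.339 with an estimated correlation). The collagen gene Col1a1, chosen after its values were seen, was at 19.3 and 0.785 in the wild-type libraries. The maternal list (1 higher of 7) had a median of −0.194 and a mean of 0.133, the stress list (1 higher of 25) a median of −0.12 and a mean of 0.00422, and the cumulus list (1 lower of 9) a median of 0.012 and a mean of −0.0342, so median and mean differed in sign. None had an adjusted camera p under 0.05. X-linked genes had a median of 0.39 over 443 genes, against 0.108 for the highest autosome, and made up 28 of 248 higher calls. They were also 11 of 64 higher calls with miR-344-2 (Fisher's exact test across genes, not independent replicates, p = 1.22e-05), where the X median was 0.2 against 0.06 for the highest autosome, and 7 of 183 with MERVL. In total 248 genes were higher and 131 lower, and 27 were called in a fit on the compared groups only. The count was 1383 without wild-type replicate 2. The Gt/Gt and wild-type cells are 1 line each, so line differences other than Zmym2 are included.

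A second question was what MERVL activation changed in CRISPRa cells. Zscan4c rose from 3.05 ± 1.11 to 32.4 ± 15 (log2 fold change 3, adjusted p = 0.00051), with Zscan4f (3.89 ± 2.2 to 45.3 ± 20.3), Zscan4e (0.937 ± 0.599 to 14.1 ± 4.95), Zscan4d (2.94) and Zscan4a (2.59). This family marks two-cell embryos and the rare two-cell-like state of stem cells. Arl14epl rose from 0.471 ± 0.0733 to 9.55 ± 0.342, Ndufa4l2 from 3.36 ± 2.32 to 32 ± 15, and the defensin gene Defb25 was at 9.41 ± 2.3 against a control listed at 0. Of 33 two-cell-stage genes 25 rose and 0 fell (29 and 0 adjusted over the list alone), among them Gm2016 (3.21), Gm2022 (3.16) and Gm8300 (3.1). All 33 were positive, with a median of 1.75 (camera adjusted p = 2.2e-54). Spink3 (chromosome 18, start 43887722, end 43896891), a trypsin-inhibitor gene, went from 139 ± 9.51 to 23.5 ± 5.55 and Ccnd2, a cyclin gene, from 4.79 ± 0.545 to 1.41 ± 0.144. Fgfbp1 (−1.33), Enox1 (−1.12), Tnnc1 (−1.1), Ankrd33b (−1.02), Accsl (−0.916) and Cend1 (−0.815) also fell. Dux, which encodes a homeobox activator of two-cell-stage genes, was at 0.849 and 0.538 with MERVL and at 0.104 and 0.0885 in EV, below the 1 FPKM filter.

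Germline genes had 4 higher and 0 lower of 26 with MERVL (5 and 0 adjusted over the list alone). The meiosis gene Stra8 rose from 1.63 ± 0.0921 to 7.6 ± 1.1 and Sohlh2 from 6.53 ± 0.485 to 21.1 ± 4.46, with Tuba3a (1.2) and Fkbp6 (1.09). The list gave adjusted p = 2.88e-06 (adjusted p = 0.298 with an estimated correlation). Ddit4, a stress-induced inhibitor of mTOR signalling, rose from 11.9 ± 5.09 to 47.1 ± 8.45 as the only stress gene called of 25. The list had 5 higher and 0 lower adjusted over the list alone (adjusted p = 0.00616, or adjusted p = 0.298 with an estimated correlation). Krt19 rose by 1.19 as the only trophectoderm gene called of 18 (4 and 0 adjusted over the list alone; adjusted p = 0.00616, or adjusted p = 0.41 with an estimated correlation), and Serpine2 by 1.21 as the only cumulus marker of 9 (adjusted p = 0.00769, or adjusted p = 0.298 with an estimated correlation). No fibroblast marker was called, although all 15 were positive with a median of 1.09 (0.0294 in replicate 1 and 1.42 in replicate 2; adjusted p = 2.03e-05, or adjusted p = 0.323 with an estimated correlation). The corepressor list had no calls and a median of −0.0902 (adjusted p = 0.0278, or adjusted p = 0.323 with an estimated correlation), and Zmym2 was at 19.3 ± 10.1 against 28.2 ± 18.9. No pluripotency, primitive endoderm, primed, imprinted, maternal or compaction gene was called, and their list p-values were 0.793, 0.125, 0.827, 0.125, 0.0896 and 0.707. In all, 183 genes were higher and 15 lower. Fitted on the compared groups only, 2 genes were called. Col1a1, chosen after its values were seen, was at 9.38 and 0.272 in the EV libraries and at 9.99 and 8.53 with MERVL.

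The same question was asked of miR-344-2 activation. Arl14epl rose from 0.471 ± 0.0733 to 20.4 ± 6.94 (3.83, adjusted p = 0.000158), Fmr1nb, an X-linked testis antigen gene (chromosome X, start 66015013, end 66057735), from 1.8 ± 0.0356 to 38.4 ± 3.3, and Usp26 from 0.0643 ± 0.0562 to 12.4 ± 4.59. Apoa2, an apolipoprotein gene, rose from 0.138 ± 0.196 to 12.8 ± 1.36 and Ube2l6 from 1 ± 0.206 to 10.4 ± 1.59. Tmem40 rose from 2.36 ± 0.3 to 16.9 ± 3.16, Nlrp4f, an oocyte gene, from 0.42 ± 0.0727 to 5.75 ± 1.86, and Calml4 by 2.54. Only a few named genes fell: Fgf15 (8.17 ± 0.77 to 3 ± 0.0396), a growth-factor gene, Accsl (−1.04) and Lonrf2 (−0.927). None of 33 two-cell-stage genes was called over all genes, and 5 rose and 0 fell adjusted over the list alone. Of the 33, 32 were positive with a median of 0.493 (0.442 and 0.489 by replicate, and 0.318 to 0.624 as single libraries were left out; camera adjusted p = 9.24e-20, or adjusted p = 0.0663 with an estimated correlation). Germline genes had 4 higher and 0 lower of 26 (5 and 1 adjusted over the list alone), Sohlh2 (21.6 ± 0.0573), Stra8 (1.48), Fkbp6 (1.42) and Tuba3a (23 ± 2.28 against 8.89 ± 0.527), with adjusted p = 1.8e-10 (adjusted p = 0.0955 with an estimated correlation). Trophectoderm genes had 2 higher and 0 lower of 18 (5 and 0 adjusted over the list alone), Krt19 (0.749 ± 0.181 to 3.73 ± 0.747) and Krt7 (0.759), with adjusted p = 4.88e-10 (adjusted p = 0.102 with an estimated correlation).

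Ddit4 rose with miR-344-2 as well (53.4 ± 21.9), the only stress gene called of 25. The list median was 0.341 (2 and 0 adjusted over the list alone; adjusted p = 3.16e-06, or adjusted p = 0.0906 with an estimated correlation). The maternal list had 1 gene higher of 7 and a median of 0.372 (adjusted p = 0.00767, or adjusted p = 0.0955 with an estimated correlation). Pluripotency and imprinted lists had 1 gene higher each, and primitive endoderm (median −0.0938, mean 0.0356), primed, corepressor, compaction, fibroblast (median −0.497) and cumulus lists had none. No adjusted camera p of these was under 0.05. Zmym2 was at 17.6 ± 9.09 against 28.2 ± 18.9 (−0.571, adjusted p = 1). In all, 64 genes were higher and 6 lower, and 0 were called in a fit on the compared groups only. Set directly against MERVL activation, miR-344-2 gave 27 genes higher and 205 lower, or 45 and 133 with median-ratio scaling, and the median of all genes was −0.104. Of 33 two-cell-stage genes 0 were higher and 21 lower (0 and 26 adjusted over the list alone; median −1.08, camera adjusted p = 9.96e-26), including Zscan4c (6.24 ± 3.02 against 32.4 ± 15), Zscan4f (−2.27) and Gm5662 (−2.42). Defb25 (−2.98), Ifi27l2a (−2.69), Crxos1 (−2.06) and the matrix gene Postn (0.00696 ± 0.00984 against 6.45 ± 4.39) were also lower. Fgfbp1 (2.06), Fmr1nb (1.48), Apoa2 (1.48), Usp26 (1.46), Calml4 (1.44), Spink3 (1.44), Snrpn,Snurf (1.33) and Perp (1.26) were higher. Fibroblast markers had 0 higher and 1 lower of 15 (1 and 10 adjusted over the list alone; adjusted p = 9.53e-06, or adjusted p = 0.57 with an estimated correlation), and the imprinted list had a median of 0.29 without calls (adjusted p = 0.0079, or adjusted p = 0.194 with an estimated correlation).

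**Figure D2:**
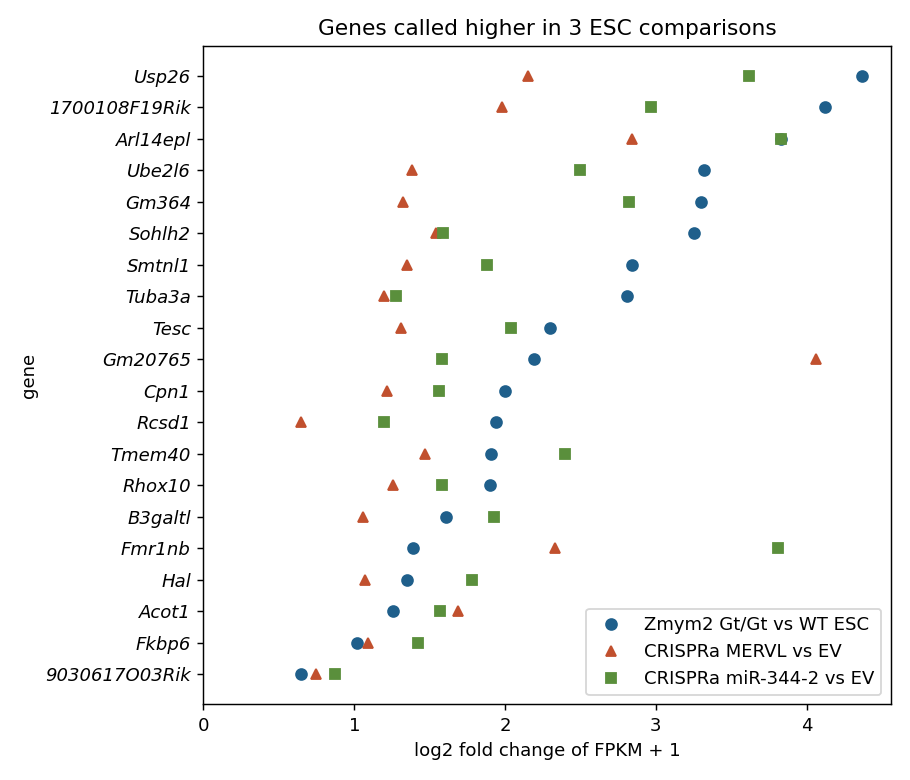
Log2 fold changes of the 20 genes called higher in Gt/Gt, CRISPRa MERVL and CRISPRa miR-344-2 cells. Usp26 was at 4.37, 2.15 and 3.62 and Arl14epl at 3.83, 2.84 and 3.83.

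Genes called higher in Gt/Gt cells were then read in the CRISPRa cells. With MERVL 30 of the 100 Zmym2-higher genes rose and 0 fell (92 positive, median 0.742; camera adjusted p = 2.12e-41, and 0.000904 with an estimated correlation). With miR-344-2 29 rose and 0 fell (92 positive, median 0.809; adjusted p = 1.12e-83, and 5.8e-05 with an estimated correlation). Of the 100 genes 7 were in the two-cell-stage list and 9 were X-linked. The Zmym2-lower genes had 3 higher and 2 lower with MERVL (adjusted p = 0.759) and 3 higher and 0 lower with miR-344-2 (median 0.0697; adjusted p = 0.00761, or adjusted p = 0.224 with an estimated correlation). Higher calls shared by Gt/Gt and MERVL numbered 49 against 3.6 expected (Fisher's exact test p = 1.94e-42), and lower calls 3 against 0.156, while 5 genes lower in Gt/Gt were higher with MERVL and 1 the other way. Gt/Gt and miR-344-2 shared 39 higher calls against 1.26 expected (Fisher's exact test p = 3.29e-51) and 0 lower calls, while 3 genes lower in Gt/Gt were higher with miR-344-2. The 20 genes higher in all 3 comparisons included the germ-cell genes Sohlh2 (3.25, 1.54, 1.59), Fkbp6 (1.02, 1.09, 1.42), Tuba3a (2.81, 1.2, 1.28) and Rhox10 (1.9, 1.26, 1.58), and also Ube2l6 (3.32, 1.38, 2.5), Smtnl1 (2.84, 1.35, 1.88), Tesc (2.3, 1.31, 2.04), the acyl-CoA thioesterase gene Acot1 (1.26, 1.69, 1.57) and the histidine-lyase gene Hal (1.35, 1.07, 1.78). None of the 20 was in the two-cell-stage list and 4 were X-linked. MERVL and miR-344-2 share their EV control. They shared 31 higher calls against 0.928 expected from group sizes and 4 lower against 0.00713. The covariance of 0.041 across genes, not independent replicates, stood beside 0.0633 simulated from shared control noise alone. That simulation takes libraries as independent, while replicate-number differences correlated at 0.864 to 0.894 among these groups, so its value may be too high. With a replicate block 82 higher calls were shared. Part of the excess may come from the shared controls.

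The next question was what MERVL and miR-344-2 changed in DR++ cells. DR++ EV stood apart: with DR++ UT as control 38 of 56 and 25 of 54 named genes changed sign, the 38 without a call. With MERVL the two-cell-stage list had 30 genes higher and 0 lower of 33 (30 and 1 adjusted over the list alone; median 2.78, camera adjusted p = 1.24e-40), but with DR++ UT as control its median was −0.0669 (adjusted p = 0.249). Zscan4c went from 0.354 ± 0.0243 to 25.7 ± 1.1, Zscan4d from 0.394 ± 0.117 to 21.7 ± 0.442, and Gm5662, BB287469 and Usp17lb rose by 4.69, 3.77 and 3.33. Pluripotency genes had 8 higher and 1 lower. Those higher included Nanog (74.7 ± 3.51 to 390 ± 1.76), Klf4 (22.8 ± 1.24 to 138 ± 2.46), Zfp42 (171 ± 1.62 to 612 ± 3.06) and Nr0b1 (2.08; adjusted p = 0.00012, or adjusted p = 0.248 with an estimated correlation). Germline genes had 13 higher and 1 lower of 26, including Mael (2.11; list adjusted p = 2.71e-06, or adjusted p = 0.261 with an estimated correlation). Primed genes had 4 higher and 0 lower (adjusted p = 0.0153, or adjusted p = 0.479 with an estimated correlation), and corepressor genes 3 higher, Hdac1 by 1.35. Compaction genes had 0 higher and 10 lower of 23, with the adhesion gene Cdh1 (212 ± 7.22 to 36.6 ± 1.13) and Cldn7 (−2.3) lower (adjusted p = 0.00156, or adjusted p = 0.328 with an estimated correlation). Primitive endoderm genes had 0 higher and 9 lower, the basement-membrane genes Col4a1 (34.6 ± 1.46 to 2.6 ± 0.0523) and Col4a2 (−2.86) among them (adjusted p = 7.94e-06, or adjusted p = 0.328 with an estimated correlation). Stress genes had 0 higher and 7 lower, with Ddit3 (45.1 ± 3.04 to 10.1 ± 0.677) and Cdkn1a (131 ± 11 to 48.5 ± 2.79) lower (adjusted p = 0.00253, or adjusted p = 0.261 with an estimated correlation). Trophectoderm genes had 2 higher and 6 lower, Krt18 at 7.99 ± 0.289 against 44.1 ± 1.66. Imprinted genes had 4 and 4 (median 0.0244, mean −0.336), fibroblast markers 0 and 3 (median 0.0724, mean −0.0329), cumulus markers 0 and 1, and maternal genes none. The largest falls also held Krtdap (−3.46), Nnat (−3.28), Ifi30 (−3.04), Gstm3 (−2.95) and the chaperone gene Hsp90b1 (561 ± 15.1 to 79.8 ± 0.41). In all, 928 genes were higher and 1250 lower. With DR++ UT as control 1 gene was called, and the pluripotency, compaction and stress medians were 0.0415, 0.122 and 0.112, none with a list p under 0.05.

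With miR-344-2 in DR++ cells 28 two-cell-stage genes were higher and 1 lower of 33 (29 and 2 adjusted over the list alone; median 1.85, adjusted p = 4.33e-31), but with DR++ UT as control the median was −0.502, that of the germline list −0.204 (adjusted p = 0.129), and 55 genes were called. Zscan4c was at 25.7 ± 4.08, Zscan4d at 27.2 ± 1.95 and Zscan4a rose by 4.18. Pluripotency genes had 9 higher and 0 lower (adjusted p = 1.13e-05, or adjusted p = 0.143 with an estimated correlation), with Nanog at 440 ± 75.7, Klf4 at 141 ± 43.9, Zfp42 at 746 ± 43.6 and Prdm14 higher by 1.92. Germline genes had 6 higher and 2 lower (adjusted p = 0.000129, or adjusted p = 0.312 with an estimated correlation). Primitive endoderm genes had 0 higher and 11 lower, Col4a1 at 1.52 ± 0.622 (adjusted p = 2.46e-06, or adjusted p = 0.286 with an estimated correlation). Lower genes were also 10 of trophectoderm with 1 higher, Krt18 and Krt19 falling by 2.57 and 2.87 and Id2 by 2.98 (adjusted p = 0.00106, or adjusted p = 0.418 with an estimated correlation). Compaction genes had 0 higher and 10 lower, Cdh1 at 43.3 ± 5.55 (adjusted p = 0.000272, or adjusted p = 0.286 with an estimated correlation). Stress genes had 1 higher and 10 lower, Ddit3 at 6.01 ± 1.71 and Ddit4 at 61.2 ± 13.8 against 277 ± 0.848 (adjusted p = 0.00128, or adjusted p = 0.278 with an estimated correlation). Primed genes had 3 higher and 2 lower, corepressor genes 2 and 1, imprinted genes 3 and 6 (median 0.117, mean −0.464), maternal genes 0 and 1, fibroblast markers 0 and 3, and cumulus markers 1 and 1. The heparan-sulfate proteoglycan gene Sdc4 fell from 259 ± 11.5 to 25 ± 0.231 and Snrpn,Snurf from 42.2 ± 2.58 to 1.23 ± 0.483. In all, 770 genes were higher and 1954 lower, or 1170 and 1365 with median-ratio scaling, with a median of all genes of −0.154. Both DR++ activations share the EV control. Shared calls were 539 higher (56.6 expected) and 1089 lower (193), with a covariance of 0.439 (0.0636 simulated). Against DR++ UT 1 and 55 genes were called, so most shared calls depend on DR++ EV.

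How the controls themselves differed was asked next. Against DR++ UT, the libraries labelled DR++ EV had 0 two-cell-stage genes higher and 30 lower of 33 (median −2.74, adjusted p = 1.4e-37), Zscan4c at 0.354 ± 0.0243 against 31.5 ± 0.214 and Gm5662 lower by 4.99. Nanog (74.7 ± 3.51 against 347 ± 60.5), Klf4 (−2.44) and Zfp42 (−1.99) were among 8 pluripotency genes lower with 2 higher (adjusted p = 0.000165, or adjusted p = 0.266 with an estimated correlation). Compaction genes had 12 higher and 1 lower, Cdh1 at 212 ± 7.22 against 37.1 ± 5.02 (adjusted p = 0.00346, or adjusted p = 0.383 with an estimated correlation). Primitive endoderm genes had 9 and 0 with Col4a1 at 34.6 ± 1.46 against 2.18 ± 0.814 (adjusted p = 0.000124, or adjusted p = 0.383 with an estimated correlation), and stress genes had 7 and 0 with Cdkn1a at 131 ± 11 against 30.6 ± 5.96 (adjusted p = 0.00519, or adjusted p = 0.32 with an estimated correlation). Trophectoderm genes had 7 higher and 0 lower, Krt18 by 2.42 (adjusted p = 0.0393, or adjusted p = 0.622 with an estimated correlation). Germline genes had 2 and 9 (adjusted p = 1.45e-05, or adjusted p = 0.32 with an estimated correlation). Primed genes had 1 and 4 (adjusted p = 0.0331, or adjusted p = 0.516 with an estimated correlation), and corepressor genes 0 and 3 with Hdac1 lower by 1.45 (adjusted p = 0.0393, or adjusted p = 0.438 with an estimated correlation). Imprinted genes had 4 and 2 (median −0.135, mean 0.335), fibroblast 3 and 0, cumulus 1 and 1, and maternal 1 and 0. The glutathione-transferase gene Gstm3 was at 24.6 ± 1.47 against 0.827 ± 0.339. In all, 2021 genes were higher and 1039 lower, or 1652 and 1375 with median-ratio scaling, and the median of all genes was 0.121. Chromosome 8 genes had a median of 0.554 against 0.285 for the second-highest chromosome.

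Set against unsorted CRISPRa EV, a contrast that also differs in batch, DR++ EV had 2806 genes higher and 1625 lower, or 2406 and 2178 with median-ratio scaling, around an all-gene median of 0.119. Ddit4 was at 277 ± 0.848 against 11.9 ± 5.09, Cdkn1a at 131 ± 11 against 12.6 ± 5.03 and the annexin gene Anxa2 at 186 ± 8.79 against 11.2 ± 1.29. In the stress list 14 genes were higher and 0 lower of 25 (adjusted p = 0.00315, or adjusted p = 0.459 with an estimated correlation). Ndufa4l2 (4.83), Gstm3 (4.23), Sdc4 (4.06), Krt19 (3.81) and Col4a1 (3.55) were higher, and Acat3 (−5.02), Dusp27 (−4.39), Gbx2 (−3.9) and Nr0b1 (12.6 ± 0.589 against 125 ± 38.7) lower. Pluripotency genes had 1 higher and 10 lower (adjusted p = 0.000394, or adjusted p = 0.459 with an estimated correlation). Compaction genes had 13 and 2 (adjusted p = 0.00943, or adjusted p = 0.469 with an estimated correlation), trophectoderm genes 9 and 0 (adjusted p = 0.000436, or adjusted p = 0.469 with an estimated correlation), and primitive endoderm genes 10 and 0 (adjusted p = 0.000394, or adjusted p = 0.469 with an estimated correlation). Corepressor genes had 2 higher and 7 lower (adjusted p = 0.0159, or adjusted p = 0.469 with an estimated correlation). Two-cell-stage genes had 4 and 5 with Zscan4c lower by 1.55 (median −0.18, adjusted p = 0.0339, or adjusted p = 0.705 with an estimated correlation). That list was not called either with a mean of at least 5 FPKM (−0.743), on the compared groups only (−0.754), with median-ratio scaling (−0.186), or without CRISPRa EV replicate 2 (−0.0886) or DR++ EV replicate 1. Germline genes had 7 and 2, imprinted 6 and 5, primed 3 and 3, fibroblast 4 and 0 (median 0.0216, mean −0.0167), cumulus 3 and 1, and maternal 1 and 0.

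Comparisons with DR++ UT as control were added after the data had been seen. DR++ MERVL against DR++ UT had 1 call, Eef1a1, which was listed at 0 in DR++ UT and DR++ EV, with 366 genes at an unadjusted p under 0.05. DR++ miR-344-2 against DR++ UT had 10 genes higher and 45 lower, with 0 two-cell-stage genes higher and 6 lower of 33 (0 and 13 adjusted over the list alone; median −0.502, adjusted p = 3.96e-20, or adjusted p = 0.0628 with an estimated correlation). DR++ UT against CRISPRa EV had 381 genes higher and 183 lower. There 32 two-cell-stage genes were higher and 0 lower (median 2.6, adjusted p = 6.56e-67), 8 germline genes were higher (adjusted p = 5.14e-12, or adjusted p = 0.137 with an estimated correlation), and 27 Zmym2-higher genes were higher and 3 lower (adjusted p = 1.98e-12, and 0.04 with an estimated correlation). Trophectoderm genes had 5 and 0 (adjusted p = 6.55e-05, or adjusted p = 0.45 with an estimated correlation) and stress genes 4 and 1 (adjusted p = 0.0308, or adjusted p = 0.45 with an estimated correlation).

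Whether activation changed genes differently in DR++ and unsorted cells was tested as an interaction, which contains both EV controls. For MERVL 419 genes were higher and 993 lower, or 668 and 869 with median-ratio scaling (all-gene median −0.13). The two-cell-stage list had 14 higher and 0 lower (median 1.06, adjusted p = 1.39e-13, or adjusted p = 0.185 with an estimated correlation), Usp17lc by 1.69. Nanog (2.15), Nr0b1 (2.58) and Spink3 (3.67) were higher, and Cdh1 (−2.67), Krt18 (−2.96) and Nnat (−4.35) lower. For miR-344-2 364 genes were higher and 802 lower, or 547 and 698 with median-ratio scaling (all-gene median −0.109), with 23 two-cell-stage genes higher and 1 lower (median 1.36, adjusted p = 1.5e-20, or adjusted p = 0.059 with an estimated correlation). Zscan4a (3.8), Zscan4c (3.49), Zfp42 (2.98) and Nanog (2.36) were higher, and Snrpn,Snurf (−5.5), Krt19 (−4.3) and Ddit4 (−4.25) lower. With DR++ UT in place of DR++ EV, added after the data had been seen, the interactions had 3 genes higher and 24 lower for MERVL and 12 and 76 for miR-344-2. The two-cell-stage medians were then −1.56 (adjusted p = 6.76e-101, and 0.000181 with an estimated correlation) and −1.15 (adjusted p = 2.17e-40, and 0.00638 with an estimated correlation).

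In embryos the question was what Zmym2 siRNA or miR-344 mimic changed at the 8-cell stage, against 1 NC library. In siZmym2 embryos of normal morphology 1 gene was called, the small nucleolar RNA Snora7a (74.4 ± 9.02 against a control listed at 0), with 27 genes at an unadjusted p under 0.05 in limma. Two-cell-stage genes had 0 calls of 42 and a median of −0.028 (adjusted p = 0.438), and the stress list a median of −0.275 without calls (adjusted p = 0.00633, or adjusted p = 0.108 with an estimated correlation). With miR-344 mimic 0 genes were higher and 2 lower, Dppa3 and Map1lc3b, both listed at 0 in the mimic libraries, and 147 had an unadjusted p under 0.05. The two-cell-stage median was 0 (adjusted p = 0.342). Mimic against siZmym2 embryos gave 3 lower calls, Dppa3, Map1lc3b and Snora7a, all listed at 0 with mimic. Dux was listed at 0 in NC and normal siZmym2 embryos, at 1.73 ± 2.44 with mimic and at 1.15 ± 0.828 in arrested embryos. Neither the Zmym2-higher list nor any other list had a call in these normal-morphology comparisons beyond the genes named.

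Arrested siZmym2 embryos were compared with siZmym2 embryos of normal morphology. Zfp352 (chromosome 4, start 89885510, end 89892378), a retrotransposed zinc-finger gene of the two-cell stage, rose from 0.623 ± 0.536 to 58 ± 42 (5.01, adjusted p = 0.0066), Gm5662 from 3.51 ± 2.49 to 130 ± 17.7, and the oocyte-type homeobox gene Obox3 from 1.09 ± 0.529 to 39.8 ± 28.2. Gm5039 (4.66), Gm8300 (4.53), BB287469 (3.75) and the oocyte gene Rfpl4b (3.85) also rose, as did Gm20765 (0.481 ± 0.262 to 76.6 ± 28.6, chosen after its values were seen). Of 42 two-cell-stage genes 7 were higher and 0 lower (24 and 0 adjusted over the list alone; 38 positive, median 1.89, camera adjusted p = 5.12e-36), and the all-gene median was 0.119. By replicate the list stood 1.89 and 1.91 above normal siZmym2 embryos, while Zfp352 was at 87.7 and 28.3 and Zscan4c at 4.67 and 24. Stress genes had no calls, with 21 of 24 positive and a median of 0.726 (adjusted p = 0.000298). Pluripotency genes had none either, with a median of −0.497 (adjusted p = 0.00037, or adjusted p = 0.0952 with an estimated correlation). That median was 0.19 (adjusted p = 0.278) without arrested replicate 0. The maternal list had a median of 0.411, 0.938 and −0.237 by replicate. The Zmym2-higher list had 3 genes higher of 76 (adjusted p = 0.0396, or adjusted p = 0.357 with an estimated correlation), and stood at −0.135 and 0.474 in replicates 0 and 1. In all, 12 genes were higher and 2 lower, the latter being Lypd8 and Snora7a, both listed at 0 in arrested embryos. Calls numbered 1 to 71 as single libraries were removed. Against the NC library 0 genes were called by limma, with 364 at an unadjusted p under 0.05. The two-cell-stage list had 21 genes higher and 0 lower adjusted over the list alone (39 positive, median 1.98, adjusted p = 1.96e-35). The pluripotency list had a median of −0.439 (adjusted p = 0.00439, or adjusted p = 0.245 with an estimated correlation), which was 0.17 without arrested replicate 0. The imprinted list was at −0.308 (adjusted p = 0.0179, or adjusted p = 0.393 with an estimated correlation), and the Zmym2-higher list 0.222 (adjusted p = 0.0198, or adjusted p = 0.314 with an estimated correlation).

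**Figure D3:**
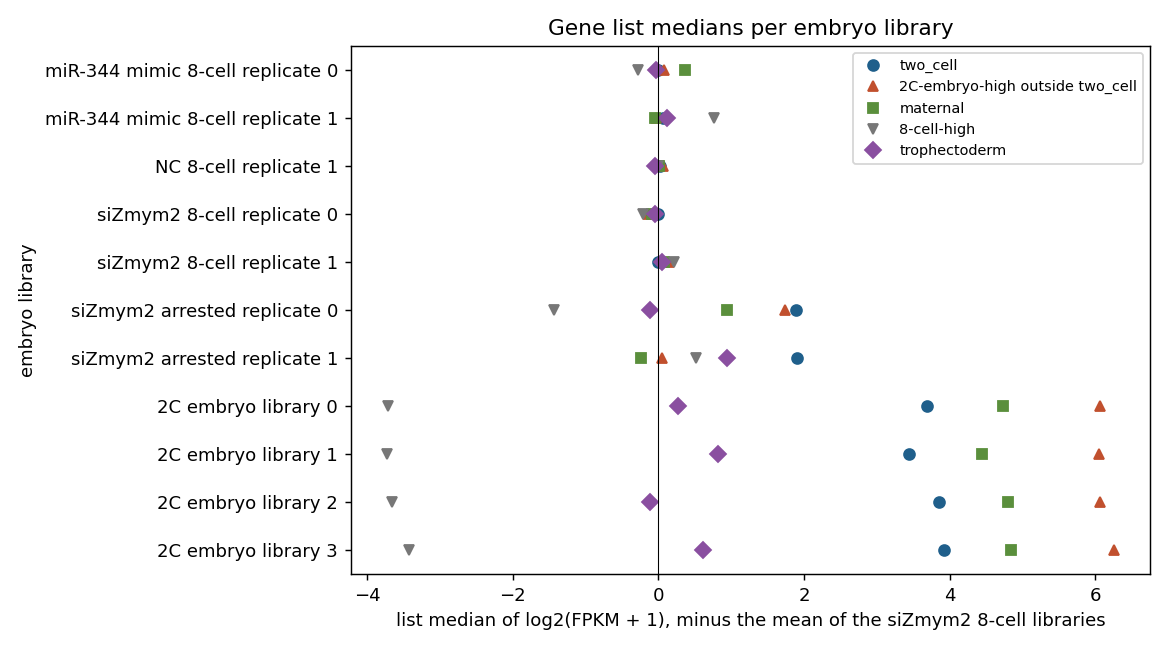
List medians per embryo library, as log2(FPKM + 1) minus the mean of normal siZmym2 8-cell libraries. Two-cell-stage genes stood at 1.89 and 1.91 in the arrested libraries and at 3.44 to 3.92 in two-cell embryos.

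As a reference for stage, two-cell embryos (n = 4) were compared with normal-morphology 8-cell embryos (n = 5), a contrast that also differs in batch and injection. Tcl1, an AKT cofactor gene, was at 3260 ± 990 against 6.97 ± 4.03, and Oosp1, an oocyte-secreted protein gene, at 2210 ± 1330 against 4.35 ± 2.23. Btg4, a maternal mRNA-clearance gene, was at 1920 ± 348 against 7.49 ± 3.88, and Zbed3 was higher by 8.13. Usp17lb (351 ± 121 against 1.76 ± 1.48), Zfp352 (152 ± 33.4 against 1.02 ± 0.475), Zscan4d (112 ± 43.7 against 1.28 ± 2.3) and Gm13078 (6.99) were among 39 two-cell-stage genes higher with 1 lower of 41 (median 3.65, adjusted p = 1.57e-05, or adjusted p = 0.055 with an estimated correlation). The all-gene median was 1.18, and list medians are to be read against it. Maternal genes had 29 higher and 1 lower of 30 (median 4.63, adjusted p = 6.56e-06, or adjusted p = 0.0687 with an estimated correlation) and germline genes 23 and 1 of 29, Brdt by 6.79 (median 2.35, adjusted p = 0.0289, or adjusted p = 0.0687 with an estimated correlation). Pluripotency genes had 7 higher and 7 lower of 25, Nanog (0.431 ± 0.862 against 17.8 ± 12.2) and Tdgf1 (1.71 ± 0.748 against 150 ± 43.2) lower. The list median was −0.338 and its mean 0.181 (adjusted p = 0.000968, or adjusted p = 0.055 with an estimated correlation). Gata6 (3.46 ± 1.69 against 41 ± 11.2), Cbx3 (−3.08), Cldn4 (−3.05), Fbp2 (−6.71), Bhmt (−6.44) and Sycn (−7.28) were lower, and Prl3b1 was listed at 0 in two-cell embryos (80.7 ± 18 in 8-cell). Zmym2 was higher (8.57 ± 1.11 against 1.73 ± 0.852; 1.86, adjusted p = 4.48e-05), by 0.741 with median-ratio scaling (adjusted p = 0.0268). Kdm1a was not called (0.176), and with median-ratio scaling it was called lower (−1.16, adjusted p = 0.00784). Calls in the other lists were 9 higher and 2 lower for trophectoderm, 7 and 1 for primitive endoderm, 11 and 0 for primed, and 21 and 1 for corepressor. They were 9 and 1 for imprinted, 13 and 5 for compaction, 14 and 5 for stress, 1 and 0 for fibroblast, and 3 and 0 for cumulus, none with an adjusted camera p under 0.05. In all, 8159 genes were higher and 1495 lower, or 5259 and 3527 with median-ratio scaling.

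Genes called higher in two-cell embryos were looked up in stem cells, where 104 of 200 were tested. In Gt/Gt cells 9 rose and 1 fell (median 0.00606) and with MERVL 9 and 1 (median 0.13, adjusted p = 0.0182, or adjusted p = 0.251 with an estimated correlation). The counts were with miR-344-2 3 and 1 (0.0254, adjusted p = 0.0235, or adjusted p = 0.342 with an estimated correlation), and in DR++ UT against CRISPRa EV 13 and 2 (0.215, adjusted p = 5.45e-05, and 0.0475 with an estimated correlation). The 8-cell list had no calls of 176 with miR-344-2 (median 0.135, adjusted p = 5.75e-06, or adjusted p = 0.342 with an estimated correlation), and 57 genes higher and 13 lower in DR++ EV against UT (0.509, adjusted p = 0.00909, or adjusted p = 0.558 with an estimated correlation). Camera calls holding with an estimated correlation were two-cell-stage genes in CRISPRa MERVL against EV, miR-344-2 against MERVL and DR++ UT against CRISPRa EV. They also held in DR++ EV against UT, both interactions with DR++ UT, and arrested embryos against either reference. In DR++ MERVL and miR-344-2 against EV they held, but not with DR++ UT as control. Stress genes held in arrested against normal siZmym2 embryos. The Zmym2-higher list held in both CRISPRa comparisons and DR++ UT against CRISPRa EV, and the two-cell-embryo list in the latter.

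Blastocysts had 1 library per group, so the values have no replicate check. Compared with NC, Gata3, a trophectoderm factor gene, was at 123 (mimic) and 27.5 (siZmym2) against 11.3, the water-channel gene Aqp3 at 54.2 (mimic) against 4.39, and the sodium-pump gene Atp1b1 at 59.5 and 48.9 against 13.3. Tet2 was at 28.4 (mimic) and 9.96 (siZmym2) against 3.08, Sall4 at 103 and 49.6 against 18.7, Cbx3 at 2700 and 638 against 196, and Gata6 at 35.8 and 33.7 against 11.6. Of the two-cell-stage genes, Arg2 was at 8.78 (siZmym2) against 2.03 and Ddit4l at 22.9 and 17.6 against 7.34. Medians of all 7846 genes were 0.569 (mimic) and 0.57 (siZmym2), and the list medians that follow are not corrected for this shift. Compaction genes had medians of 1.45 (percentile 100 of 10000 matched random lists) and 1.01 (96.9), and germline genes 0.159 (2.01) and 0.32 (6.32). For mimic and siZmym2 in turn, percentiles were 20.2 and 21.9 for two-cell-stage, 92.1 and 33.7 for pluripotency, 87.9 and 45.8 for trophectoderm, 75.4 and 44 for primitive endoderm, 35.3 and 13.2 for corepressor, 77 and 86.9 for imprinted, 55.5 and 59.9 for maternal, and 45.8 and 62.4 for stress genes.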

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

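The tests of the 3 patterns in this section were chosen after the results had been seen, except the test of X-chromosome dosage and the test of other splits of the embryo libraries, which were written before; the tests of Y loss and of an XX line were also changed once after the values had been seen.

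Several two-cell embryo libraries stood apart from the other 3 in single measures. The number given for each is the share of the range taken up by the gap to the nearest library. Library 3 had a total FPKM of 943000 against 634000 to 665000 (0.9) and 6.45% of FPKM in the largest gene against 1.96 to 2.6% (0.856). In log2(FPKM + 1), library 3 was lower for Tcl1 (10.8 against 11.8 to 11.9; 0.854), Usp17lb (7.43 against 8.61 to 8.77; 0.876) and Gm13078 (6.13 against 7.3 to 7.42; 0.907). The same library was higher for Sycp3 (9.29 against 7.73 to 7.98; 0.836) and Kdm1a (4.75 against 3.6 to 3.75; 0.871). Library 2 was lower for Tubb3 (3.89 against 5.28 to 5.56; 0.83) and Gata4 (4.46 against 5.17 to 5.28; 0.856). Library 1 alone had Nanog (1.45) and Vnn1 (0.235) above 0, and library 0 alone had Sycn (2.24) above 0, each with a gap of 1 because the others were listed at 0. Of 77 such measures 12 passed the gap bound, against 3.85 expected by chance at about 1 in 20 groups. A difference in composition or amplification of library 3 is possible and was not tested, as its total FPKM is itself 1 of these measures.

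The activation effects differed between DR++ and unsorted CRISPRa cells. For MERVL 1412 genes were called in the interaction. Median interactions were 1.06 for two-cell-stage, 0.602 for pluripotency, 0.33 for primed and 0.406 for corepressor genes. They were −0.853 for trophectoderm, −1.01 for primitive endoderm, −0.609 for compaction, −0.871 for stress and −1.15 for fibroblast lists. For miR-344-2 1166 genes were called, with medians of 1.36 for two-cell-stage, 1.09 for pluripotency, 0.546 for primed and 0.467 for corepressor genes. The trophectoderm, primitive endoderm, compaction and stress medians were −1.51, −1.12, −0.759 and −1.1. None of these lists was called with an estimated correlation (two-cell-stage adjusted p = 0.185 and 0.059). With DR++ UT as control 27 and 88 genes were called, with two-cell-stage medians of −1.56 and −1.15. The other medians shrank to −0.667 to 0.117 (MERVL) and −0.816 to 0.326 (miR-344-2). The sign of the two-cell-stage interactions depends on the control. DR++ UT was untreated and already high for these genes, and batch is confounded with population, so why effects differed stays open.

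In the libraries labelled DR++ EV, two-cell-stage genes were low, with Zscan4c at 0.354 ± 0.0243 (n = 2) against 31.5 ± 0.214 in DR++ UT. A median of −2.75 under median-ratio size factors argues against scaling by a few abundant genes, and collagen genes up to 0.928 FPKM against feeder reads. The 4431 calls against CRISPRa EV (564 for DR++ UT) argue only against that group under this label. A mislabelled population from outside these groups fits, since the highest correlation with a library of another group was 0.943 across genes, not independent replicates, while the other DR++ groups reached 0.962 to 0.996 among themselves. A separate subline predicts that value too, and chromosome 8 genes had a median of 0.554 against DR++ UT, which fits a gain of chromosome 8. Malat1, a nuclear RNA gene chosen after its values were seen, was at 185 and 177 against 48 and 72.9, and whether the vector, a subline, a label, cell state or RNA quality accounts for the loss of Zscan4c stays open, so changes against DR++ EV may describe the control as much as the activation.

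Arrested siZmym2 embryos had high two-cell-stage genes, Zfp352 at 87.7 and 28.3 FPKM in replicates 0 and 1. A few abundant genes as the cause are argued against by a list median of 1.97 under median-ratio size factors, although Bc1 alone held 82.4% of FPKM in arrested replicate 0. Replicate 0 may simply be at an earlier stage, because two-cell-embryo genes outside the list were higher by 1.74. The same explanation is argued against for replicate 1, where that value was 0.055 while the two-cell-stage list stood at 1.91, but Obox6, chosen after its values were seen, was at 180 in this library, between blastocysts (9.94 to 26.2) and the other embryo libraries (548 to 1730). What remains open is whether the state of replicate 1, 1 library, would be seen again, and whether Zmym2 siRNA or arrest itself accounts for it, as arrested control embryos were not compared.

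Y-linked genes were low in Gt/Gt cells: Ddx3y was at 0.439 and 0.919 against 13.4 and 67.8, Eif2s3y at 1.63 and 4.26 against 29.4 and 123, and Uty at 0.137 and 0.564 against 4.43 and 20.8. Y-linked reads from feeder cells are argued against, since Y-linked genes were higher by 2.02 in wild-type replicate 2, the replicate with low collagen. Neither loss of the Y chromosome nor an XX line compared with an XY line, for which the X median stood 0.283 above the highest autosome, can be decided with Eif2s3y still at up to 4.26, and Ddx3y (0.433 and 1.3) and Uty (0.0119 and 0.0357) were as low in CRISPRa EV cells that had Eif2s3y at 37.7 and 90.1. A fall of Y-linked genes after loss of Zmym2 cannot be decided from siZmym2 embryos, where the median was −0.667 against 1 NC library, nor can X dosage, whose median of 0.39 lies just under the bound of 0.4 set in advance. Any of these could add to the 28 X-linked genes called higher, Usp26 among them, but X-linked genes were also 11 of 64 higher calls with miR-344-2 in CRISPRa cells, so line identity and Zmym2 loss stay confounded.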

How the results depend on the processing

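Groups of 2 libraries, 1 control library at the 8-cell stage and 1 line per genotype limit all results, and the cause of each shift given here was not tested. The alternatives that were planned are named in the processing notes. A fit lacking DR++ EV, DR++ UT as control, a fit lacking two-cell embryos, removal of genes listed at 0, and the same alternatives for derived lists and overlaps were chosen after seeing the data. Other read alignments, count-based models, transcript-level values, repeat families and removal of library pairs were not run. Below, list values are median log2 fold changes with adjusted camera p.

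With a mean of at least 5 FPKM, calls numbered 104 for Gt/Gt, 52 for CRISPRa MERVL, 20 for CRISPRa miR-344-2, 21 for miR-344-2 against MERVL, 977 for DR++ MERVL, 1289 for DR++ miR-344-2, 1481 for DR++ EV against UT and 2415 against CRISPRa EV. The interactions had 562 (MERVL) and 386 (miR-344-2), siZmym2, mimic and arrested against NC 6, 7 and 10, and two-cell against 8-cell embryos 5512. The fibroblast list turned positive with miR-344-2 (0.164, 0.0273), and the two-cell-stage list in DR++ EV against CRISPRa EV was not called (−0.743, 0.0608). Of the Zmym2-higher and Zmym2-lower lists in miR-344-2 against MERVL, the first turned to −0.152 (0.0577) and the second was at 0.058 (0.0725). The Zmym2-lower list was at −0.108 (0.717) with miR-344-2, −0.448 (0.165) with DR++ miR-344-2, −0.0638 (0.379) in arrested against NC and 0.0684 (0.624) against siZmym2 embryos. The two-cell-embryo list was at 0.0056 (0.318) with miR-344-2. The 8-cell list was at 0.161 (0.0035) with MERVL, 0.0122 (0.108) for miR-344-2 against MERVL and 0.621 (0.0336) in DR++ EV against CRISPRa EV. Shared higher calls were 13 for MERVL and miR-344-2, 249 for the DR++ pair, 16 for Gt/Gt and MERVL, and 8 for Gt/Gt and miR-344-2. Shared lower calls were 0, 490 and 1 for the first 3 of these. Of 389 named genes tested, 368 were the same and 21 weaker, and of the lists 159 were the same, 14 weaker, 12 stronger and 1 reversed.

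With a replicate block, calls numbered 911 for Gt/Gt, 669 for CRISPRa MERVL, 187 for CRISPRa miR-344-2, 1466 for miR-344-2 against MERVL, 4709 for DR++ MERVL, 5573 for DR++ miR-344-2, 5695 for DR++ EV against UT and 7163 against CRISPRa EV. The block gave 3678 and 3330 for the interactions, 5 for arrested against NC and 26 against siZmym2 embryos. The Zmym2-lower list was at −0.302 (0.0973) with DR++ miR-344-2. Shared higher calls were 82 (MERVL and miR-344-2), 1324 (DR++ pair), 157 (Gt/Gt and MERVL) and 88 (Gt/Gt and miR-344-2), and shared lower calls 12, 2226, 19 and 5. Zmym2 in Gt/Gt cells was called with the block, although not without it. Of the named genes 462 were the same and 2 stronger, and of the lists 187, 6 and 2 were the same, stronger and weaker. Sharing a replicate number is not a record of pairing. Differences between replicate numbers correlated across genes, not independent replicates, at 0.533 to 0.894 between unsorted stem-cell groups, −0.0926 to 0.676 between DR++ groups and 0.253 to 0.48 between embryo groups.

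In fits on the compared groups only, calls numbered 27 for Gt/Gt, 2 for CRISPRa MERVL, 0 for CRISPRa miR-344-2, 83 for miR-344-2 against MERVL, 8772 for DR++ MERVL, 4885 for DR++ miR-344-2, 6827 for DR++ EV against UT and 2548 for the MERVL interaction. They were 3 for siZmym2 and 0 for mimic against NC, and 0 for arrested against siZmym2 embryos. The two-cell-stage list in DR++ EV against CRISPRa EV was at −0.754 (0.158). Named genes were the same in 362 cases, weaker in 92 and stronger in 1, and lists in 169, 6 and 10.

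In the fit lacking DR++ EV, calls numbered 46 for miR-344-2 against EV and 127 against MERVL, and 92 named genes were the same and 22 weaker. With DR++ UT as control, calls numbered 1 for DR++ MERVL, 55 for DR++ miR-344-2 and 564 against CRISPRa EV, and 27 and 88 for the MERVL and miR-344-2 interactions. Two-cell-stage medians turned to −0.0669 (0.249) for DR++ MERVL, −0.502 (3.96e-20) for DR++ miR-344-2 and 2.6 (6.56e-67) against CRISPRa EV. For DR++ MERVL the compaction, pluripotency and stress lists were at 0.122 (0.61), 0.0415 (0.61, with the test direction turned) and 0.112 (0.785), and the germline list for DR++ miR-344-2 at −0.204 (0.129). In the MERVL interaction the two-cell-stage, germline and pluripotency lists turned to −1.56 (6.76e-101), −0.373 (2.27e-08) and 0.00576 (0.887, with the test direction turned). In the miR-344-2 interaction the two-cell-stage and germline lists turned to −1.15 (2.17e-40) and −0.674 (2.58e-09), and the primed list was at 0.0602 (0.844, with the test direction turned). With an estimated correlation the germline calls (0.204 and 0.102) and the DR++ miR-344-2 two-cell-stage call were lost. Named genes were refitted with this control except in the interactions. Of 175, 73 changed sign, 80 were weaker and 22 same, namely 38, 16 and 2 of 56 for DR++ MERVL, 25, 26 and 3 of 54 for DR++ miR-344-2, and 10, 38 and 17 of 65 against CRISPRa EV. Individual values were left out after this count was seen. In the fit lacking two-cell embryos 2 genes were called in arrested against siZmym2 embryos, and 15 named genes were the same and 8 weaker.

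A pseudocount of 0.1 gave 142 calls for miR-344-2 against MERVL and 3 for arrested against NC. The Zmym2-higher list was at 0.211 (0.231) in arrested against NC and 0.206 (0.192) against siZmym2 embryos. Shared higher calls were 58 (MERVL and miR-344-2) and 86 (Gt/Gt and MERVL), and shared lower calls of MERVL and miR-344-2 were 2. In blastocysts, relative to all genes, the primitive endoderm list was at 0.541 with mimic and the imprinted list at 0.586 with siZmym2. Named genes were the same in 504 cases and weaker in 21. No variance trend gave 134 calls for miR-344-2 against MERVL and 1 lower call shared by Gt/Gt and MERVL, with 509 named genes the same and 16 weaker. A minimum absolute log2 fold change of 1 gave 136 calls for miR-344-2 against MERVL, 1226 for DR++ MERVL, 1558 for DR++ miR-344-2 and 1796 for DR++ EV against UT.

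Without a filter, calls numbered 583 for Gt/Gt, 14, 16 and 12 for siZmym2, mimic and arrested against NC, and 5 for arrested against siZmym2 embryos. The Zmym2-higher list was at 0.188 (0.119) and 0.137 (0.266) in the arrested comparisons, and 5 lower calls were shared by Gt/Gt and MERVL. Named genes were the same in 498 cases and weaker in 27. With median-ratio size factors, calls numbered 2 for siZmym2 against NC and 32 for arrested against siZmym2 embryos, and Kdm1a in two-cell embryos turned to −1.16 (adjusted p = 0.00784). The two-cell-stage list in DR++ EV against CRISPRa EV was at −0.186 (0.107), and the Zmym2-lower and Zmym2-higher lists in arrested against siZmym2 embryos at −0.00652 (0.0617) and 0.145 (0.0617). Lower calls shared by Gt/Gt with MERVL and miR-344-2 were 6 and 2. Named genes were the same in 514 cases, weaker in 10 and reversed in 1.

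With an estimated correlation the two-cell-stage list lost its call in two-cell embryos (3.65, 0.055), CRISPRa miR-344-2 (0.493, 0.0663), DR++ EV against CRISPRa EV (−0.18, 0.705), the MERVL (1.06, 0.185) and miR-344-2 (1.36, 0.059) interactions and Gt/Gt (0.487, 0.0894). The two-cell-embryo list did so with MERVL (0.13, 0.251) and miR-344-2 (0.0254, 0.342). For the 8-cell list the values were 0.135 (0.342) with miR-344-2, −0.00263 (0.609) for miR-344-2 against MERVL, 0.509 (0.558) for DR++ EV against UT, −0.426 (0.588) for DR++ MERVL, −0.441 (0.588) for DR++ miR-344-2, and −0.724 (0.968) and −0.664 (0.665) for the interactions. The Zmym2-higher list was at 0.11 (0.205) for miR-344-2 against MERVL, −0.118 (0.498) for DR++ EV against UT, 0.268 (0.292) for DR++ MERVL, 0.205 (0.137) for DR++ miR-344-2, 0.222 (0.314) for arrested against NC and 0.15 (0.357) against siZmym2 embryos. The Zmym2-lower list was at 0.0697 (0.224) with miR-344-2, 0.0554 (0.205) for miR-344-2 against MERVL, −0.302 (0.327) for DR++ miR-344-2, −0.0715 (0.314) for arrested against NC and 0.0202 (0.357) against siZmym2 embryos. In all, 73 fixed-list results were weaker and 135 the same.

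With 100 genes per stage list, the two-cell-embryo list was at −0.00154 (0.0888) with miR-344-2, −0.0901 (0.0218) with DR++ MERVL and 0.157 (0.0176) in Gt/Gt. The 8-cell list was at −0.0405 (0.195) for miR-344-2 against MERVL and −0.417 (0.0656) for DR++ miR-344-2. With 50 genes the Zmym2-lower list was at 0.0778 (0.0656) for miR-344-2 and −0.249 (0.0976) for DR++ miR-344-2.

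As single libraries were left out, calls ranged from 131 (without Gt/Gt replicate 1) to 1383 (without wild-type replicate 2) for Gt/Gt, 44 (without MERVL replicate 2) to 93 (without replicate 1) for CRISPRa MERVL, and 19 (without EV replicate 2) to 32 (without EV replicate 1) for CRISPRa miR-344-2. The ranges were 7 to 54 for miR-344-2 against MERVL, without MERVL replicates 2 and 1, and 717 to 848 for DR++ MERVL, without DR++ EV replicate 1 and DR++ MERVL replicate 2. Without DR++ EV replicate 1 calls fell to 884 of up to 2043 for DR++ miR-344-2, 1204 of up to 1769 (without UT replicate 1) for DR++ EV against UT, 2459 of up to 3914 against CRISPRa EV, 561 of up to 1165 for the MERVL interaction and 429 of up to 909 for the miR-344-2 interaction. They ranged from 0 (without siZmym2 replicate 1) to 1 for siZmym2 against NC, from 1 (without arrested replicate 0) to 18 (without arrested replicate 1) for arrested against NC, and from 1 (without siZmym2 replicate 0) to 71 (without arrested replicate 1) against siZmym2 embryos. Counts moved by more than 1.5 times without either wild-type or Gt/Gt library in Gt/Gt, without any single library in the CRISPRa comparisons, in DR++ MERVL, in DR++ EV against UT, and in both arrested comparisons. They did so without either DR++ EV library against CRISPRa EV, and without either DR++ EV library or DR++ miR-344-2 replicate 2 for DR++ miR-344-2. In the MERVL interaction each library but CRISPRa EV replicate 1 did so, and in the miR-344-2 interaction either DR++ EV library, CRISPRa EV replicate 2, CRISPRa miR-344-2 replicate 1 and DR++ miR-344-2 replicate 2. The compaction list in Gt/Gt ranged from −0.423 to 0.0572 (without wild-type replicate 1), the fibroblast list with miR-344-2 from −1.04 to 0.0638 (without EV replicate 1), and the two-cell-stage list in DR++ EV against CRISPRa EV from −0.225 to −0.0886 (without EV replicate 2). The maternal list ranged from −0.166 to 0.8 in arrested against NC and from −0.237 to 0.938 against siZmym2 embryos, negative without arrested replicate 0 in both. Named genes were the same in 2317 cases, weaker in 430 and stronger in 1, and lists in 852, 40 and 27 with 4 reversed.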

Other observations

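Some transcripts were listed at 0 in whole groups although they were abundant elsewhere. Eef1a1, a translation elongation factor gene, was listed at 0 in DR++ UT and DR++ EV with a median of 6202 FPKM in the other libraries. Dppa3, a maternal protector of DNA methylation, and Map1lc3b, an autophagy gene, were listed at 0 in all 3 mimic libraries with medians of 21910 and 4742 elsewhere in embryos. The neuronal RNA gene Bc1 was listed at 0 in the 4 two-cell libraries and in the mimic blastocyst, and held up to 82.4% of FPKM in arrested replicate 0.

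The tests in this paragraph on the Zmym2-higher list were chosen after the result was seen, and the test of other splits was written before. The Zmym2-higher genes were also higher with miR-344-2, and the median was 0.808 without two-cell-stage members and 0.788 without X-linked genes. Leaving out 7 or 9 of 100 genes could not have moved the median far, so this decides nothing. One hypothesis is that Zmym2 loss and miR-344-2 act on shared genes such as Sohlh2, Fkbp6 and Arl14epl. These also rose with MERVL (1.54, 1.09 and 2.84). A test would measure Zmym2 protein after miR-344-2 activation and read Sohlh2 and Arl14epl in several independent Gt/Gt and wild-type lines of known karyotype. Another hypothesis is that the gene trap line differs in sex chromosomes, which karyotyping would decide. Between two-cell and 8-cell embryos 9654 genes were called, against at most 6824 in other splits (1 of 100 as large, the least possible). This argues against chance, but not batch, injection or FPKM composition.

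For arrested embryos a hypothesis is that Zmym2 is needed to silence Zfp352, Gm5662 and Obox3. Replicate 1 kept two-cell-stage genes high without other two-cell-embryo genes (0.055), although maternal RNAs among the latter may be lost with time. Normal siZmym2 embryos (Zmym2 1.05 and 0.914, arrested 0.973 and 1.07) had Zfp352 at 0.244 and 1 and a two-cell-stage median of −0.028 against NC. NC Zmym2 was 2.82 (8-cell) and 1 (blastocyst), so stage confounds this. The hypothesis rests on 1 library, which across genes, not independent replicates, correlated at 0.942 with the NC blastocyst (NC 8-cell 0.939). The alternative that arrest itself delays silencing could be tested with control embryos arrested by another means and staged by cell number. For DR++ cells, a new empty-vector transfection of sorted cells, read for Zscan4c and for chromosome 8 copy number, would show whether the median of 0.554 is a property of that culture.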
